A study of Arabidopsis thaliana with 2 samples.

How the data were processed

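Total RNA from whole inflorescences of flowering Arabidopsis thaliana plants of the Col-0 accession was labelled with Cy3 and hybridised to one-colour Agilent oligonucleotide arrays of design 021169, per the labels and the file headers. There was 1 array of plants that carry ERF19 behind the cauliflower mosaic virus 35S promoter, a strong promoter that is active in most plant tissues, and 1 array of wild-type plants. The labels do not say how many plants went into each RNA. With 1 array per genotype there was no estimate of the spread between plants, so no test between genotypes was made and no p-value is given. Both arrays lay on 1 slide, so slide could not be used as a block.

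The spot intensity values were made by the authors with Agilent Feature Extraction 9.1, per the submitters' processing notes, whereas the file headers name the protocol GE1_105_Dec08 and component version 10.5.1.1. The deposited intensity of a spot was its processed signal, which is background-subtracted and detrended across the array with no normalisation between arrays, per the file headers. Each array held 45220 spots, of which 43803 were not controls and covered 43603 probes. A further deposited table of the authors gave the same intensities and a log2 ratio to wild type after quantile normalisation, per its header. Its median was 0.03 in the 35S::ERF19 column of log2 ratios and 0 in the wild-type column, and its direction was 35S::ERF19 over wild type. In that table the probe names stood 1 row above the values they belong to. With the names moved by 1 row, 99.9% of the 35S::ERF19 and 99.9% of the wild-type intensities equalled those of the scanner files within 0.1%, against 0.046% and 0.028% as listed. The table was therefore used only through the moved names.

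The scanner signals were taken as log2 values, and the 75th percentile over non-control spots without an outlier flag on either array was subtracted from each array. Spots of a probe were averaged. Probes were given genes through the RefSeq accessions of the array files (34697 probes), otherwise through a locus tag (1213) or a current symbol (597), all looked up without versions in a table of the TAIR10.1 assembly that was used for names only. Of the 43603 probes, 36007 had 1 gene, 500 had several and 7096 had none. Probe positions are those of the array files, whose grid was built on TAIR10. The value of a gene was the median over its probes that the scanner called well above background on at least 1 array, and all ratios are 35S::ERF19 minus wild type. No spot was saturated. A gene that was not well above background on 1 array had only a bound, which set its bright value against the higher of the dim array's lowest well-above-background signal and the gene's own dim signal. The bound, or 0 where the bound passed 0, stood in for the ratio of such genes in counts and in list medians. That choice was made after the measured ratios had been seen, and the measured ratios were kept as an alternative.

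Errors are technical only. The scanner's own signal error was propagated to each log2 ratio and had a median of 0.20 over genes. The 49 probes with at least 4 usable spots gave a median SD between spots of 0.13 on the log2 ratio. It was 0.08 for the 35 of them well above background on both arrays and 0.52 for the other 14. A gene was called higher or lower at a ratio of at least 2-fold, a log2 ratio of 1. The steps were tested on simulated arrays with this scanner error: 20 pairs with no differences, and 1 pair of 24881 genes in which some genes were set apart by known folds. The 2-fold threshold was passed by 2% of the genes set 1.5-fold apart, 54% of those set 2-fold apart, 100% of those set 4-fold apart and 95.9% of those set 8-fold apart, and by 0.04% of the 24682 unchanged genes of that pair. In the simulations the well-above-background call was approximated by a signal over the lowest that the scanner called so on that array.

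Before the data were examined, the normalisation, the threshold, the gene lists and the rule for the genes named were fixed. The rule named ERF19; the 12 highest and 12 lowest ratios among genes well above background on both arrays whose so-measured probes all passed 2-fold in 1 direction; the 5 largest bounds in each direction; and up to 4 members with the largest absolute log2 ratio in each list. Of the 26 lists, ERF19 alone formed 1, and the other 25 had at least 5 measured members. A list's median was placed among the medians of 10000 random lists of the same size matched on mean signal in 20 bins. The resulting percentile describes these 2 arrays and is not a test between genotypes, since genes are not replicates. A median outside the central 95% of the random medians is said to stand apart. The list rule took a symbol's locus from the reference table where that gave another gene. This put an aconitate hydratase in the place of the ethylene-forming oxidase ACO3, and an exordium-like gene in the place of EXL5, so the medians with the intended genes were added as an alternative after the values had been seen.

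Lists of seed coat, early endosperm, embryo sac, and anther dehiscence and filament genes were written after the main values had been seen and before those of their own members were looked up. Members of the fixed lists were left out of them, after a first run that had held some.

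The alternatives were median scaling, no scaling, quantile normalisation, loess of the log2 ratio on mean signal with a span of 0.3, normexp background correction with an offset of 50, a filter requiring both arrays above background, no filter on dim probes, the brightest probe or the mean over probes, the authors' processed table, and thresholds of 1.5-fold and 3-fold on the counts. With no replicates, a gene's value was taken as moved where it shifted by more than its own signal error, a list median where it shifted by more than the median signal error, and a count where it shifted by more than 1.5 times. These limits were set after the main values had been seen. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and normexp in R 4.3.3 with limma 3.58.1.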

Results

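Transcript levels were measured in whole inflorescences of Arabidopsis plants that express ERF19, a transcription factor of the ethylene response factor family, from the 35S promoter, and of wild-type plants. There was 1 array per genotype, so the precision is limited by that number and no difference below has a replicate check. The ± values are the scanner's signal error on the log2 ratio. Of the 43803 non-control spots, 91.8% were well above background on the 35S::ERF19 array and 93.8% on the wild-type array. The median processed signal was 1262 and 1399. The signals of the 24230 genes well above background on both arrays had a Pearson correlation of 0.98 across genes, which are not independent replicates.

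The first comparison asked whether the plants labelled 35S::ERF19 held more ERF19 transcript. The ERF19 probe (AT1G22810, chromosome 1, 8074537 to 8074596 on TAIR10) had a processed signal of 13951 on the 35S::ERF19 array and 47.1 on the wild-type array. The log2 ratio was 8.28 ± 0.28, or 309.7-fold, with 254.5-fold to 376.9-fold at 1 error to either side. It was the highest ratio among genes well above background on both arrays. The level in wild type lay near the lowest well-above-background signal of that array, 22, and the log2 ratio was 6.49 with normexp background correction. The probe does not separate transcript of the transgene from that of the resident gene.

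The second comparison asked which other genes differed between the genotypes. The genes with the lowest ratios included 3 that code for chitinases, a glucanase gene and a glutathione transferase gene, and those with the highest included 2 peroxidase genes and a pair of transporter genes. Of 24844 genes measured, 367 were at least 2-fold higher and 930 at least 2-fold lower in the 35S::ERF19 array. At 4-fold the counts were 68 higher and 246 lower, and at 8-fold 25 higher and 73 lower. With quantile normalisation, 467 genes were higher and 729 lower, so that 61% of the genes apart were lower in place of 71.7%. The excess of lower genes lay among dim genes. With the genes in 5 equal groups by mean signal, 125 of the dimmest group were higher and 510 lower, against 35 higher and 29 lower in the brightest group. Of the 202 genes 2-fold apart with several probes, 191 had all probes on the same side of 0 and 109 had all probes at least 2-fold apart.

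**Figure D1:**
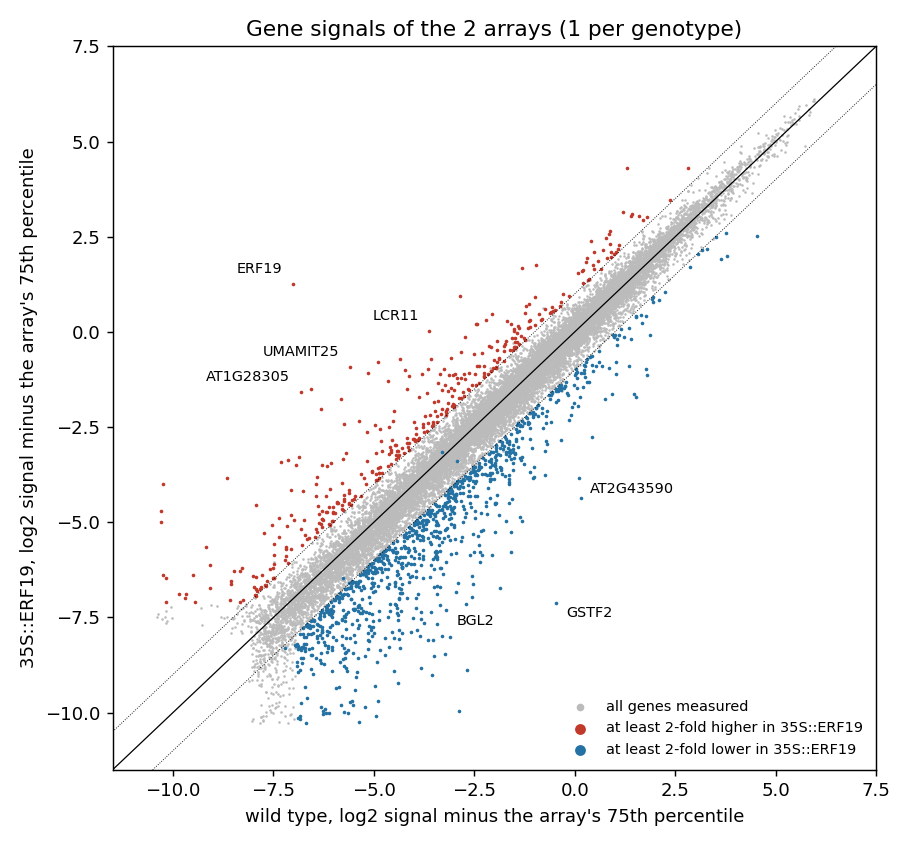
Gene signals of the wild-type array (x axis) and the 35S::ERF19 array (y axis), each as log2 processed signal minus the array's 75th percentile, with 1 point per gene (the median over its probes). The solid line marks equal signals and the dotted lines 2-fold; the 367 higher genes are red, the 930 lower genes blue, ERF19 stands farthest from the line, and called genes inside the dotted lines have several probes, whose median ratio differs from the ratio of the medians.

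After ERF19, the highest ratio was that of AT1G28305, a gene of the self-incompatibility protein S1 family, at 5.24 ± 0.24 or 37.9-fold. The peroxidase genes AT5G19880 and AT3G03670 were 33.4-fold and 16.8-fold higher, whereas of the 58 genes described as peroxidases, a group looked up after the values were seen, 6 were at least 2-fold higher and 15 lower, with a median of -0.18 at the 1.25th percentile. UMAMIT25 (AT1G09380), of a family of amino acid transporters, was 25.6-fold higher at 4.68 ± 0.22, and ATCHX13 (AT2G30240), a cation/proton exchanger gene, 13.8-fold higher. LCR11 (AT4G11485), a cysteine-rich peptide gene, was 12.4-fold higher at a log2 ratio of 3.64 ± 0.21. The pectin methylesterase inhibitor gene AT1G70720 was 13.9-fold higher and the dehydrin gene AT4G39130 16.5-fold higher, while the glycine-rich protein gene AT1G27710 was 17.2-fold higher. The uncharacterised genes AT4G13266 and AT3G55570 were 19.8-fold and 14.8-fold higher. All of these were read by 1 probe each.

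The lowest ratio was that of GSTF2 (AT4G02520), a glutathione S-transferase gene, at -5.74 ± 0.15 or 53.4-fold lower, with 3 probes between -6.64 and -5.36. Among the 12 lowest were 3 chitinase genes: AT1G02360 was 21.9-fold lower, AT2G43570 (CHI) was lower at a log2 ratio of -4.19 ± 0.22, and AT2G43590 was 15.5-fold lower. BGL2 (AT3G57260), the pathogenesis-related glucanase of the salicylate response, was 17.2-fold lower at -4.10 ± 0.34. The proteinase inhibitor gene AT5G43570 was 17.2-fold lower. The receptor kinase gene CRK6 (AT4G23140) had a median log2 ratio of -4.44, from a probe at -3.29 and another at -5.60 that was not well above background on the 35S::ERF19 array. AT2G30810, described as a gibberellin-regulated protein, was 20.9-fold lower, and the esterase or lipase gene AT2G31540 14.6-fold lower. The uncharacterised genes AT1G63057, AT2G30766 and AT1G13520 were 29.4-fold, 22.7-fold and 14.9-fold lower.

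For genes well above background on 1 array only, 94 were so on the 35S::ERF19 array and 520 on the wild-type array. The largest bounds on the 35S::ERF19 side were AT5G67010, another ERF family gene, at least 19.6-fold higher, and TCP16 (AT3G45150), a transcription factor gene, at least 17.5-fold higher. APRR6 and MLO9 were at least 10.7-fold and 8.73-fold higher. LCR2 was 10.4-fold higher, which is its measured ratio and not a limit. Its wild-type signal lay above the lowest well-above-background signal of that array. No bound allows for the signal error of the log2 ratio, which was 1.45 for TCP16, 1.39 for APRR6 and 1.44 for MLO9. On the wild-type side, the FAD-binding berberine-type oxidoreductase genes AT1G26420 and AT1G30700 were at least 38.8-fold and 33.8-fold lower in the 35S::ERF19 array. The protein kinase gene AT1G70450 was at least 29-fold lower, AT1G58225 at least 26.6-fold lower and the defensin-like gene AT1G13609 at least 25.1-fold lower.

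The gene lists were then compared between the genotypes. Genes of the ethylene response were lower as a group: 7 of 19 members were at least 2-fold lower and 0 higher, and the list's median log2 ratio was -0.53, below all 10000 matched random lists. They included the chitin-binding protein gene HEL at -1.83 ± 0.20, ERF2 at -1.77 ± 0.21 and OSR1 at -1.57 ± 0.20. EDF2, counted among the 7, had -0.92 at its 1 probe well above background on both arrays. Its other probes, at -2.31 and -2.08, were not well above background on the 35S::ERF19 array, and it came under 2-fold in 3 of 11 alternative settings, with -0.70 nearest to 0. Of the 15 genes of ethylene perception and signalling 0 passed 2-fold. Their median was -0.16, at the 3.85th percentile and under the 2.5th in 3 of 11 settings, with values of -0.96 for EIL2, -0.92 for ETR2, 0.36 for EIN4 and -0.32 for ERS2. Ethylene biosynthesis genes went both ways. The ACC oxidase genes ACO5 and ACO1 were higher at 2.17 ± 0.21 and 1.11, the latter from a probe at 1.47 and another at 0.76 that was not well above background on the wild-type array. The ACC synthase genes ACS2 and ACS8 were lower at -1.95 ± 0.21 and -1.31 ± 0.23, and the median of 11 members was -0.27, at the 7.73th percentile and under the 2.5th in 1 of 11 settings. With the intended ACO3 in place of an aconitate hydratase gene it was -0.45, at the 0.95th percentile. Among 12 close relatives of ERF19 only ERF010 passed 2-fold, at 1.09 ± 0.20, and the median was 0.06, at the 88.1th percentile. ERF014 had 0.71 and ERF009 0.48, and ERF021 had a bound of -0.72.

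**Figure D2:**
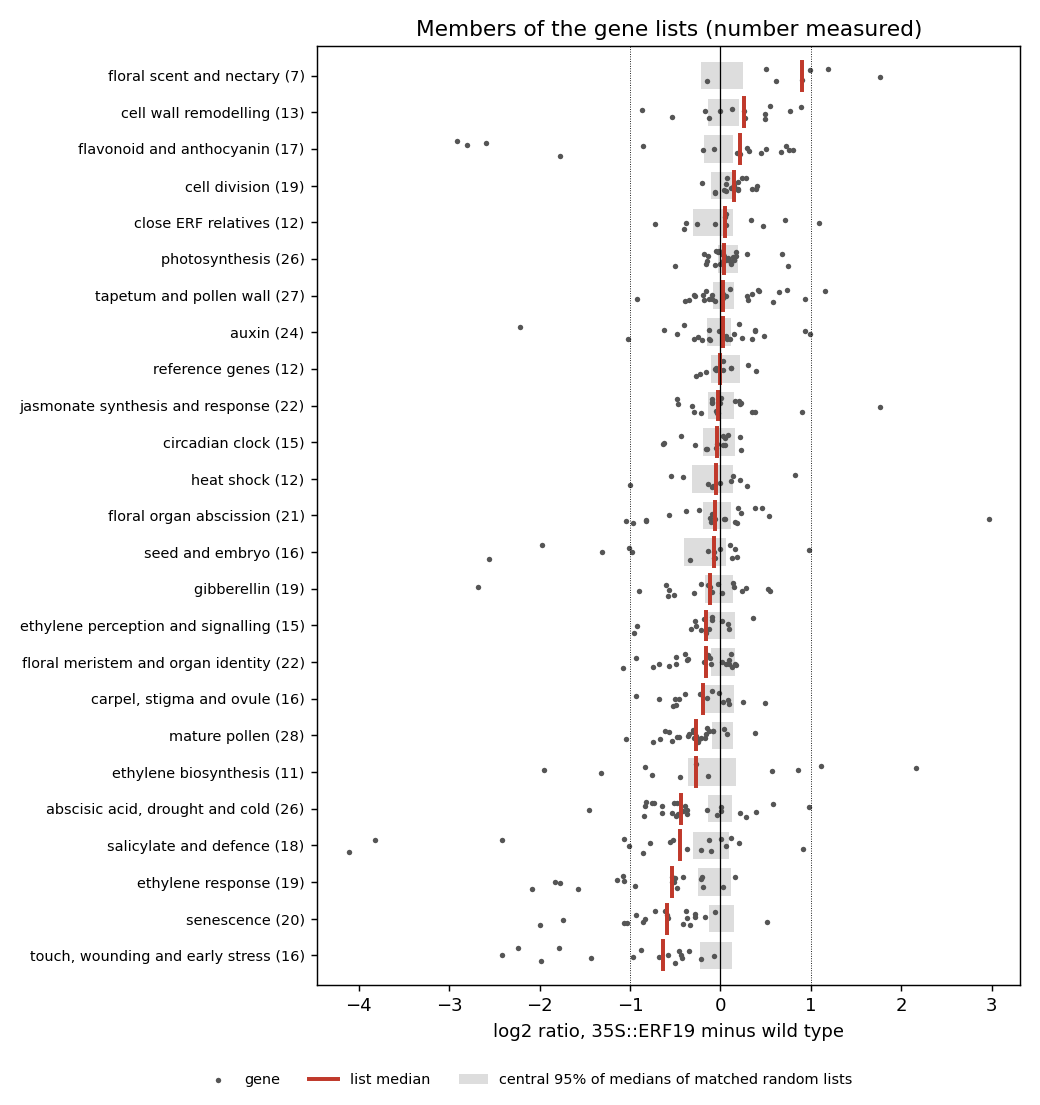
Log2 ratios (35S::ERF19 minus wild type, x axis) of the measured members of 25 gene lists, with 1 point per gene, the list median as a red line and the central 95% of medians of matched random lists as a grey bar. The medians run from -0.63 for touch, wounding and early stress to 0.90 for floral scent and nectary.

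Of the 4 lists of stress and defence genes, 3 had medians that stood apart below the random lists, and heat shock did not. For touch, wounding and early stress, 5 of 16 members were at least 2-fold lower, 0 had a ratio above 0, and the median of -0.63 was below all 10000 random lists. Their largest values were those of WRKY40 at -2.41 ± 0.15, the calmodulin-like TCH3 at -2.24 ± 0.14, MYB15 at -1.98 ± 0.15 and WRKY46 at -1.78 ± 0.14. For salicylate and defence, 5 of 18 were lower and 0 higher, with a median of -0.45 at the 0.11th percentile. Besides BGL2 they included PAD3, of camalexin synthesis, at -3.81 ± 0.29, CBP60G at -2.41 ± 0.22 and SARD1 at -1.07 ± 0.21, which came under 2-fold in 5 of 11 settings. The pathogenesis-related genes PR5 and PR1 had 0.91 and 0.21; they were named after their values were seen. For abscisic acid, drought and cold, 1 of 26 was lower, the abscisic acid synthesis gene NCED3 at -1.45 ± 0.22, and the median was -0.44, below all 10000 random lists. ERD10 had 0.98, RD26 -0.84 and KIN2 -0.83. Among 12 heat shock genes HSP17.4 had -1.0 ± 0.24, at the threshold and under it in 5 of 11 settings, and HSP18.2, HSP17.6C and HSP21 had 0.82, -0.54 and -0.41; the median of -0.05 was at the 60.1th percentile.

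Senescence genes were also lower as a group, with 4 of 20 at least 2-fold lower, 0 higher and a median of -0.59, below all 10000 random lists. SAG12, a cysteine protease gene, had -1.998 ± 0.12 as the median of 3 probes between -2.02 and -0.39, SEN1 had -1.74 ± 0.14 and NAP -1.03 ± 0.14. WRKY53 had -1.07, but its 2 probes stood at -2.24 and 0.10, so no direction is given for it although it counts among the 4. In the floral organ abscission list, ADPG1, a polygalacturonase gene of organ separation, was higher at 2.97 ± 0.21 and the receptor kinase gene EVR lower at -1.04 ± 0.20. IDA had -0.97 and ZFP2 -0.82, and the median of 21 members was -0.06, at the 37.0th percentile.

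Floral scent and nectary genes were higher as a group, with a median of 0.90 over 7 members, above all 10000 random lists. At least 2-fold higher were 2 of them, MYB21, a regulator of stamen and nectary development, at 1.77 ± 0.20 and the sesquiterpene synthase gene TPS21 at 1.19 ± 0.20, while the nectary sugar transporter gene SWEET9 had 0.997, just under the threshold, and MYB24 had 0.90 over 3 probes between 0.78 and 2.14. MYB21 was also the only member of 22 past 2-fold in the jasmonate list, where the median was -0.02 at the 30.9th percentile and JAZ1 and AOC3 had -0.48 and -0.47. Mature pollen genes had a median of -0.27 over 28 members, below all 10000 random lists, and 1 was at least 2-fold lower, the sugar transporter gene STP6 at -1.05 ± 0.20. ACT12 had -0.74, PRF4 -0.67 and CPK34 -0.62. Among 27 genes of tapetum and pollen wall AMS was higher at 1.16 ± 0.20, LAP5, MS2 and MYB80 had 0.94, -0.93 and 0.74, and the median of 0.03 was at the 41.5th percentile.

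Among 22 genes of floral meristem and organ identity, WUS, which maintains the stem cells of the meristem, was lower at -1.07 ± 0.20 and the median was -0.16, at the 0.42th percentile. SHP1, SEP1 and STK had -0.93, -0.75 and -0.68. Of the 16 genes of carpel, stigma and ovule 0 passed 2-fold, and CRC, SHP1, SHP2 and STK are also in the floral identity list. The lowest value was the -0.93 of SHP1, and INO and STY1 had -0.52 and -0.50. The median of -0.19 was at the 1.47th percentile, and the list did not stand apart in 3 of 11 alternative settings. In the seed and embryo list 4 of 16 members counted as lower, among them BAN, of seed coat proanthocyanidin synthesis, at -2.55 ± 0.20, the storage albumin gene SESA4 at -1.97 ± 0.22, and the endosperm gene PHE1 at -1.31 ± 0.21. CRA1, the other of the 4, had -0.29 at its 1 probe well above background on both arrays and -1.31 and -1.01 at probes that were not so on the 35S::ERF19 array, and it came under 2-fold in 8 of 11 settings. The median of -0.07 was at the 74.1th percentile.

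In the flavonoid and anthocyanin list 4 of 17 members were at least 2-fold lower and 0 higher, while 10 had ratios above 0. UF3GT had -2.92 ± 0.21, DFR -2.81 ± 0.14, LDOX -2.59 ± 0.21 and the regulator MYB75 -1.78 ± 0.20. The other 13 members did not pass 2-fold, and the list's median of 0.21, at the 99.6th percentile, and its mean of -0.37 differed in sign. The seed coat genes TT12, AHA10 and TT2, from a list written after the main values had been seen, were lower at -2.22 ± 0.21, -1.98 ± 0.20 and -1.62 ± 0.20. In the auxin list GH3.2 and GH3.5, which conjugate auxin to amino acids, were lower at -2.22 ± 0.23 and -1.02 ± 0.12, IAA5 and IAA6 had 0.99 and 0.94, and the median of 24 members was 0.03, at the 71.4th percentile. GA3OX4 was the only gibberellin gene of 19 past 2-fold, lower at -2.68 ± 0.35. GA20OX2, GID1C and GA2OX2 had -0.89, -0.60 and -0.58, and the median of -0.12 was at the 8.5th percentile.

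In the lists of growth and basic functions 0 genes passed 2-fold. Cell wall remodelling genes had a median of 0.27 over 13 members, at the 99.7th percentile, with EXPA1 at 0.89, XTH24 at -0.86, XTH4 at 0.77 and EXPB3 at 0.55. The 19 cell division genes had a median of 0.15, at the 95.9th percentile, and PCNA1, CYCB2-2, MCM2 and CYCA1-1 had 0.41, 0.40, 0.35 and 0.28. The 26 photosynthesis genes had a median of 0.04, at the 16.5th percentile, with RBCS1B at 0.75, RBCS2B at 0.68, LHCB3 at -0.50 and RBCS3B at 0.30. The 15 clock genes had a median of -0.04, at the 36.7th percentile, with RVE1 at -0.64, BOA at -0.62, FKF1 at -0.44 and TOC1 at -0.28. The 12 reference genes had a median of -0.01, at the 16.8th percentile, and ACT2, SAND, EF1A and UBC9 had 0.40, 0.31, -0.27 and -0.22.

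Of the 73 named genes other than ERF19 that passed 2-fold, 12 came under it in at least 1 of the 11 alternative settings. Besides EDF2, SARD1, HSP17.4, WRKY53 and CRA1, these were ACS8, ACO1, EVR and STP6 in 1 setting, NAP and WUS in 2 and GH3.5 in 3.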

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

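The tests of the signal-dependent offset, of the time of day and of differing plants or handling were chosen only after the values they bear on had been seen. Probes with no gene name took no part in the comparisons. Of the 6029 of them that were measured, 93 were at least 2-fold higher on the 35S::ERF19 array than on the wild-type array and 185 at least 2-fold lower. The highest was 27.3-fold higher, at chromosome 1, 20532960 to 20533019 on TAIR10, and the next was 19.7-fold higher, at chromosome 5, 10894309 to 10894368. The lowest with both arrays above background was 16.8-fold lower, at chromosome 3, 11510279 to 11510338. These probes were picked out after their values were seen.

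Of 51 defence, touch and ethylene-response genes, 17 were at least 2-fold lower on the 35S::ERF19 array, 34 did not pass 2-fold and 7 were above 0, with a median of -0.54. This group joins 3 lists already seen to have low medians, so its median is not independent evidence. A fit of the log2 ratio on signal was removed to look for an offset between the arrays that varies with signal. The defence and touch lists then kept a median of -0.44 ± 0.13 (bootstrap SD over members). These lists had already been seen to stand below random lists matched on signal. The fit could therefore hardly have brought them to 0, and it is no separate test of such an offset. The values show only that these lists lay lower than genes of like signal. The median of all 51 ran from -0.61 to -0.46 over the 11 alternative settings, that fit among them. Collection at another time of day stays open. The morning genes CCA1, LHY and PRR9 exceeded the evening genes TOC1, GI and ELF4 by 0.23 ± 0.15 (signal error), under the bound of 1. That bound was set after the 15 clock genes had been seen to run only from -0.64 to 0.23. The bound could not have been reached, so the test decides nothing. Plants or handling that differed between the samples stay open and cannot be told apart from the genotype, because there is 1 array per genotype. An effect of ERF19 expression itself stays open on the same grounds, untested.

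More genes were 2-fold lower than 2-fold higher, an excess of 563. By mean signal, the median log2 ratio ran from -0.228 in the dimmest of the equal groups of genes to 0.071 in the brightest. After the fit on signal was removed, 65.1% of the genes apart were still lower, against 61% with quantile normalisation. These values argue against a smooth offset with signal as the whole cause. The fit does not remove a difference in spread among dim genes, so such a difference stays open. Bounds made 153 of the lower and 27 of the higher calls. Among genes well above background on both arrays, 69.1% of those apart were lower. Scanner error alone gave an excess of at most 4 genes in 20 simulated null pairs. The simulation holds only that error, so other differences that act on dim probes, and the genotype, stay open, untested.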

How the results depend on the processing

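No paired analysis was possible because each genotype had 1 array, and leaving out an array was not possible either. Setting the measured ratio in place of the bound and placing the intended ACO3 and EXL5 in their lists were chosen after seeing the data. Of the 314 values recomputed for ERF19, the counts and the list medians, 307 stayed within their limits, 7 moved beyond them, and 0 of the list medians that stood apart changed sign. The limit for a list median was 0.20, larger than many of the medians, so the 307 are no measure of stability. Some lists that did not stand apart changed sign within it, such as seed and embryo, which ran from -0.135 to 0.08. With normexp the ERF19 log2 ratio was 6.49 and 560 genes were at least 2-fold lower; the offset of 50 narrows ratios of dim genes by construction. With the brightest probe per gene, the median of the ethylene response was -0.80, the cause of which was not tested, and WRKY53 had 0.10 in place of -1.07, since that probe is the one that differs. By construction a threshold of 1.5-fold gave more genes (1024 higher and 2373 lower) and one of 3-fold fewer (125 higher and 407 lower). For the other 128 named genes, 1283 recomputed values stayed within the gene's signal error, 113 moved beyond it, and 1 value of a gene at least 2-fold apart, that of WRKY53, changed sign. LHCB3 and EF1A, under 2-fold, had 0.06 and 0.23 with the brightest probe in place of -0.50 and -0.27. Of the 367 higher and 930 lower genes, 363 and 785 were called the same way after loess, and 254 and 554 with normexp. No scaling moved the median of all genes by more than 0.08. Of the 11 lists that stood apart, 10 did so in all 11 settings, and the list of carpel, stigma and ovule in 8. The settings are not independent checks. Median scaling and no scaling shift nearly all ratios alike and so hardly change a percentile. These lists hold no bound, so the measured ratios left their medians unchanged, and the authors' table was itself quantile-normalised. Signal over background limits the dim genes: 614 had only a bound.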

Other observations

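The test of the signal-dependent offset on cysteine-rich peptides, the peptide families and the embryo sac list without its members of those families were chosen only after values had been seen. Genes were grouped by their array description up to its first digit, and 255 groups of at least 12 genes, including a joined group of cysteine-rich secreted peptides, were looked at. Of these, 35 had a median under the 2.5th percentile of matched random lists and 18 were above the central 95% of them. Low medians included plant thionins at -0.74 (10 of 22 genes at least 2-fold lower), low-molecular-weight cysteine-rich peptides at -0.53 (16 of 49), defensin-like proteins at -0.47 (26 of 93), cysteine-rich receptor-like kinases at -0.49 (8 of 29) and putative WRKY transcription factors at -0.35 (12 of 42), whereas 17 genes described as WRKY DNA-binding proteins had -0.22, at the 4.72th percentile. Fasciclin-like arabinogalactan proteins had a high median of 0.37, with 2 of 15 genes at least 2-fold higher. Of these groups, the thionins, the low-molecular-weight and defensin-like peptides, the receptor-like kinases and the putative WRKY factors had medians below 0 in all 11 alternative settings, and the fasciclin-like proteins in 0.

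The joined cysteine-rich secreted peptides had a median of -0.34 over 467 genes, with 108 at least 2-fold lower and 15 higher, and the median ran from -0.41 to -0.21 over the 11 alternative settings. The group took in genes described as defensin, low-molecular-weight cysteine-rich, thionin, SCR-like, ECA1 or self-incompatibility S1 proteins. Individual members went far in both directions. AT1G13609 had a bound of -4.65, LCR73 had -4.25 and LCR61 had -3.80. On the other side AT1G28305, of the S1 family, had 5.24, LCR11 had 3.64, LCR2 had 3.38 and SCRL18 had 2.26. The values of LCR73 and LCR2 are measured ratios, though each gene was well above background on 1 array only. As members of this group they were picked out after their values were seen.

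Seed coat and early endosperm genes had a median of -0.86 ± 0.27 (bootstrap SD over members) over 15 members, all below 0 and 2 of them bounds, and the median was below all 10000 random lists. It ran from -1.30 to -0.51 over the 11 alternative settings. The middle member was AGL36, which has only a bound, beside TT1 with a measured -0.86. TT12 had -2.22, AHA10 -1.98, MINI3 -1.36 and TT16, the brightest of them, -0.45. Of the 15 members, 6 were at least 2-fold lower. The 7 seed coat genes alone had a median of -1.61, below all 10000 random lists. The 8 early endosperm genes alone had -0.685, at the 1.66th percentile, with 2 at least 2-fold lower. Among these, the brightest, AGL62, had -0.15 and AGL90 had -0.35. Embryo sac genes had a median of -0.22 ± 0.20 over 15 members, at the 3.44th percentile, and at the 7.42th without DD36, DD22 and DD9, which belong to the joined families; the EC1 genes, which also code for small cysteine-rich proteins, stayed in.

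For the cysteine-rich peptides, the joined median went from -0.345 to -0.25 ± 0.03 when the fit on signal was removed. The ± is a bootstrap SD over members, a spread between genes and not between plants. The fit took away part of the difference and left part, so a smooth offset with signal does not account for all of it. Families in this group had been picked for medians low against lists matched on signal, so that outcome was foreseeable. As a hypothesis, the 35S::ERF19 sample may have held fewer fertilised ovules and young seeds, for which the seed coat and early endosperm median of -0.86 is the test. That median leans more on the seed coat genes, so it does not by itself tell fewer seeds from lower transcripts of those genes. It also does not link the peptide genes to seeds, so why the peptide genes were lower was not tested by it. The outcome was partly foreseeable from BAN, PHE1, DFR and LDOX, which had been seen and are not in the test. The fixed seed and embryo list did not stand apart. Fewer ovules with a mature embryo sac stay open, since the median of -0.22 lay within its spread of the -0.23 at the 2.5th percentile of random lists. The prediction had not named a spread: the bootstrap SD was added after the percentile was seen, and without it the value would have counted against this explanation. An effect of ERF19 on these genes with no change in ovules or seeds stays open, untested.

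Of the 5 anther dehiscence and filament genes not in another list, MYB57 had 1.49, MYB26 0.53, MYB108 -0.53, NST1 -0.55 and NST2 -1.33. The median of these 5 was -0.53, at the 1.3th percentile, but its sign depends on which members are kept. The list as first written also held MYB21 at 1.77, MYB24 at 0.90, ADPG1 at 2.97, ADPG2 at 0.17 and QRT2 at -0.56, and the median of all 10 was 0.35, so no direction is given. In the authors' deposited table, read with the names moved by 1 row, the ERF19 log2 ratio was 8.39, and on the row where the name stands it was -0.07.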
